A study of Saccharolobus islandicus and Sulfolobus acidocaldarius with 94 samples.

How the data were processed

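The deposited series holds 94 samples in 59 groups of 2 thermophilic archaea, *Sulfolobus acidocaldarius* DSM639 and *Sulfolobus islandicus* REY15A. There are 32 Hi-C, 42 ChIP-seq (21 immunoprecipitates and 21 inputs), 18 RNA-seq and 2 marker frequency samples. Every sample was given a group from its title, and 0 samples were left unassigned. Hi-C measures how often pairs of chromosome segments are ligated to each other. Per the labels' protocols, cells were crosslinked and permeabilised, the DNA was digested with HindIII, the ends were filled in with biotin and ligated, and a control was made from purified DNA without crosslinking. ChIP-seq used custom antibodies against ClsN (coalescin, an SMC-related chromosome protein) and Rpo2, a subunit of RNA polymerase. Per the labels, 6 ChIP samples were sequenced on a GAIIx, namely the log-phase *S. islandicus* ClsN samples (2 immunoprecipitates, 2 inputs) and the Rpo2 samples (1 immunoprecipitate, 1 input). The other ChIP and the RNA samples were run on a NextSeq 500, and no comparison between groups mixed the 2 machines. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between libraries, which may be technical. The protocol text of both marker frequency samples speaks of exponentially growing cells although one of them is labelled stationary, and the sample label was followed.

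The submitters' processing notes name HiC-Pro 2.9.0, Bowtie2 2.3.2 and Salmon 0.8.2 without saying which step each was used for. The Hi-C files hold a deposited contact signal per bin pair, in 149 bins of 15 kb for *S. acidocaldarius* and 85 bins of 30 kb for *S. islandicus*. Every bin of a map sums to the same total and the diagonal is left out, so the maps were balanced before deposit, and totals differ between libraries. The ChIP files hold a deposited coverage signal per base, scaled to a common total, whose values are whole multiples of what 1 read is worth. The marker frequency files hold a deposited read signal per 1-kb window, in which the stationary-phase values are not whole and have about the log-phase mean, as seen in the values. The RNA files hold TPM and estimated counts per gene, both made by the authors, per the file headers in the layout that Salmon writes. The sequence names in the ChIP and RNA files give the coordinates used here, in bp of the deposited chromosome sequences, while for the Hi-C maps the genome build is not given in the sources used here and bins were counted from base 1.

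The files do not pair gene IDs with gene names. The reference table covers another *S. islandicus* strain with 2869 genes, and 0 of the 2223 *S. acidocaldarius* and 0 of the 2644 *S. islandicus* IDs matched it. The 26 gene lists fixed by product name before the data were examined were therefore not analysed here, and at most 2 IDs that rose and 2 that fell are named per comparison, those with the largest log2 fold change among genes past the threshold, with at least 20 TPM in the higher group and no overlap between the groups' replicates. For single libraries the rule was the size of the log2 change in TPM + 1 among genes with at least 50 TPM in either library. One list could be used, the fatty acid gene cluster Saci_1103 to Saci_1126 with the regulator gene fadR (Saci_1107), which had been fixed by ID. Saci_2091, SiRe_0055 and SiRe_1463 were chosen after their values were seen. The deletions of oriC1, orc1-1 and orc1-3 could not be checked against the maps at 30 kb, and argD and clsN were not matched to an ID by name.

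Contacts were divided by the mean contact at the same circular distance (observed over expected, O/E). Compartments were called from the first eigenvector of the Pearson correlation matrix of the mean log-phase map. Bins of positive sign, the sign that rises with expression, were called A and the others B. Compartment strength of a library is the mean log2 O/E of A-A and B-B pairs minus that of A-B pairs, for pairs at least 2 bins apart. The A/B preference of a bin is its mean log2 O/E with A bins minus that with B bins. The near-to-far ratio sets contacts at 30 to 150 kb against those at 500 kb and more. ClsN and Rpo2 occupancy is log2 of the share of immunoprecipitate signal over the share of input signal per gene or bin, in which a change is relative to the rest of the chromosome. Marker frequency is log2 of the log-phase over the stationary-phase share, smoothed with a running median over 50 kb, and maxima needed a prominence of 0.1.

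RNA was tested with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr) on the estimated counts rounded to whole numbers. Standard errors are those implied by the fold change and its F statistic. Bin preferences, bin pairs and ClsN occupancy were tested with limma 3.58.1, and p-values were adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05, two-sided. Group means of single values were compared by exact permutation of the libraries, two-sided. There, 2 against 2 libraries make 6 splits with a smallest p of 0.33, and 2 against 3 make 10 splits with a smallest p of 0.1, so 0.05 cannot be reached. Correlations across bins or genes were tested by rotating one series around the circular chromosome through every position (exact permutation, two-sided), because neighbours are not independent. Gene lists in single libraries were set against 10000 random lists matched on expression in 10 strata. The list of the fatty acid cluster was also tested with camera, with a preset correlation of 0.01 and with an estimated one. Other tools were DESeq2 1.42.0, R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

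Some limma fits on Hi-C bins, among them the stationary-phase and 15-min actinomycin fits, gave every bin the same standard error, since the spread between libraries did not differ detectably between bins. Bins of a library move together, so their adjusted p-values are too small and counts of changed bins describe how widespread a difference between these libraries is. The test of single compartment strengths does not have this limit.

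The tests were run on simulated data, those of RNA with 200 changed genes. At 2-fold, edgeR recovered 79.8% of changed genes for stationary against log phase (2176 genes), 91.0% for the fadR deletion (2192 genes) and 91.9% for 65 against 78 degrees (2488 genes). At 4-fold it recovered 95.9%, 98.0% and 98.0%, and 4.42%, 7.35% and 4.08% of its calls were false. limma was given simulated values in which 20% of features were shifted by 5 SD, and recovered 94.1% of 17 changed bins for the orc1-1 orc1-3 deletion and 100% of 17 or 30 in the other bin comparisons, with 0% to 9.09% of calls false. It recovered 99.2% to 99.7% of 714 or 2205 changed bin pairs and 98.2% to 99.6% of 445 or 529 changed ClsN genes. Smaller shifts were not simulated. The simulated limma features were independent of each other, whereas real bins of a library move together, so these false-call rates do not carry over to the bin fits. The rotation test gave a p under 0.05 in 5.55% of 2000 unrelated smooth series on 149 bins. A simulated strength of 0.1 was measured as 0.0749 on the 149-bin and 0.0897 on the 85-bin map, so strengths were understated there. The simulated domains were alternating blocks of equal length, unlike the real domains, so the size of this loss may not carry over to the real maps.

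Hi-C map totals ranged from 5.15 M to 49.2 M (median 21.4 M) and estimated RNA counts from 1.19 M to 7.92 M (median 2.00 M). The steps in the ChIP coverage gave 2.13 M to 30.6 M reads for ClsN immunoprecipitates and 3.64 M to 153 M for their inputs, but 130355 for the Rpo2 immunoprecipitate, which is 3.22 reads per base. Pearson correlations of replicates were 0.963 to 0.992 for RNA, 0.860 to 0.983 for ClsN immunoprecipitates, 0.895 to 0.996 for inputs and 0.490 to 0.992 for Hi-C. No replicates held identical values.

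The alternatives fixed before the data were examined covered the O/E mean or median, the eigenvector without the correlation step, Spearman's rho, other pseudocounts, A and B called in other untreated libraries, 20% of bins at each end, pairs at least 10 bins apart, immunoprecipitate share alone, centring on the median gene, windows of 5 kb, DESeq2 and its size factors, limma-trend on TPM, no filter on low counts, all libraries of a species in a single fit, the replicate number as a block, other smoothing of marker frequency, and each replicate left out in turn. The comparisons of actinomycin and stationary phase share their log-phase libraries, as do the 3 comparisons of replication mutants, and were not correlated with each other. The rank, adjusted, left-out and replicate-pair values of the relation between preference change and eigenvector were added after seeing the data, as were the shuffles of calls between genes.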

Results

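The data describe how the chromosomes of *Sulfolobus acidocaldarius* and *Sulfolobus islandicus*, hot-spring archaea, were folded, transcribed and bound by the SMC-related protein ClsN. Hi-C covered *S. acidocaldarius* in log phase (3 libraries), after 15 and 30 min of actinomycin D (2 each), in stationary phase (2), in the uracil-auxotrophic strain MW001 (2) and in MW001 labelled as a fadR deletion (2). In *S. islandicus* it covered log phase (3), deletions of oriC1, of orc1-1 and of orc1-1 with orc1-3 (2 each), cells before and after a cold shock from 78 to 65 degrees (2 each), and cells with an empty plasmid or a ClsN plasmid before and 4 h after arabinose (1 each). There was 1 map without crosslinking per species. ClsN ChIP-seq and RNA-seq had 2 libraries per group, except 1 each in the plasmid strains, 1 ClsN library per actinomycin time and no actinomycin or replication-mutant RNA. Rpo2 had 1 library. Hi-C map totals were 5.15 M to 49.2 M for *S. acidocaldarius* (median 11.7 M) and 7.52 M to 30.7 M for *S. islandicus* (median 23.7 M), and RNA libraries held 1.19 M to 7.92 M estimated counts.

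The log-phase maps asked whether each chromosome is divided into compartments. In *S. acidocaldarius* (2225959 bp), 72 of 149 bins of 15 kb were A and 77 were B. The A bins formed 4 domains, at 345001 to 795000, 1080001 to 1365000, 2145001 across the sequence start to 240000, and the single bin 315001 to 330000. The longest B domain was 1365001 to 2145000. A bins held the more strongly transcribed genes, with a median of 181.6 TPM for the 1188 A genes against 66.4 TPM for the 1035 B genes, and 181 of the 223 genes in the top 10% of expression (81.2%) lay in A, which held 53.4% of genes. ClsN was distributed the other way, with a mean log2 occupancy of -1.38 in A and 0.09 in B bins. Across the 149 bins, which are not independent, the eigenvector rose with expression (r = 0.67, permutation p = 0.0134; rho = 0.70, permutation p = 0.00671) and fell with ClsN (r = -0.67, permutation p = 0.0336; rho = -0.66, permutation p = 0.0537). The Benjamini-Hochberg adjusted p over the family of 4 such relations was 0.0179 for expression and 0.0336 for ClsN. The sign of the eigenvector had been set by expression, so only the size of that correlation was tested.

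In *S. islandicus* (2522992 bp), 27 of 85 bins of 30 kb were A and 58 were B. The A bins formed a long domain at 1050001 to 1800000 and a short one at 120001 to 180000. The 919 A genes had a median of 170.5 TPM and the 1725 B genes 56.0 TPM. Of the 265 genes in the top 10% of expression, 191 (72.1%) lay in A, which held 34.8% of genes. Mean log2 ClsN occupancy was -1.17 in A and 0.19 in B bins. The eigenvector rose with expression (r = 0.65, rho = 0.63) and fell with ClsN (r = -0.76, rho = -0.71) across bins, each r with a permutation p of 0.0118, the smallest that 85 rotations can give, and an adjusted p of 0.0179 over the 4 relations. Between libraries, the mean log2(TPM + 1) of A genes was 7.57 ± 0.01 and of B genes 5.74 ± 0.05 (SD, n = 2), against 7.66 ± 0.07 and 6.10 ± 0.04 in *S. acidocaldarius* (SD, n = 2).

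**Figure D1:**
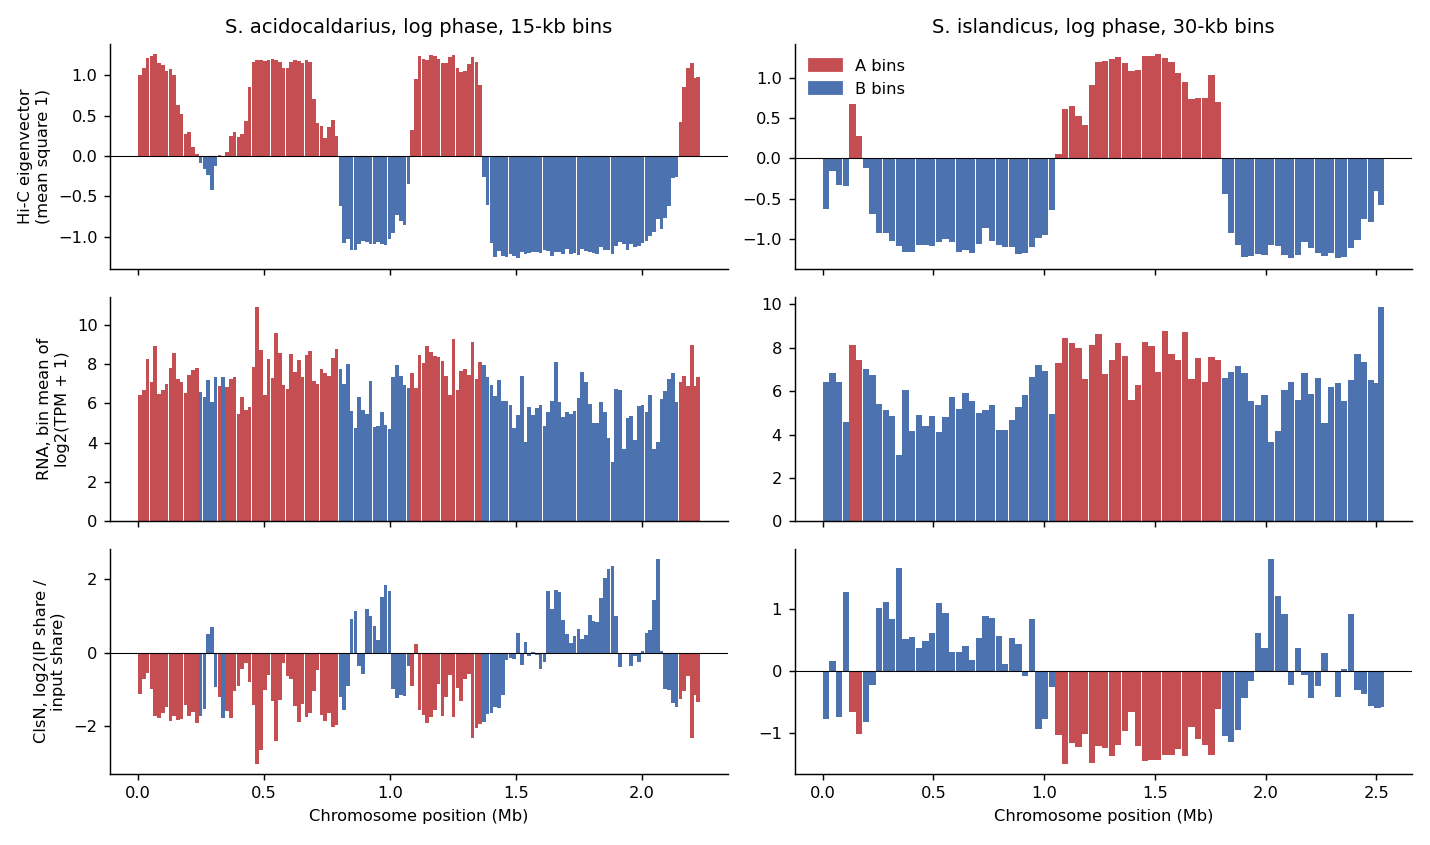
Bars per bin along the chromosome (position in Mb) of *S. acidocaldarius* (149 bins of 15 kb) and *S. islandicus* (85 bins of 30 kb) in log phase, with A bins in red and B bins in blue, for the Hi-C eigenvector, the bin mean of log2(TPM + 1) and ClsN occupancy as log2 of immunoprecipitate over input share. ClsN lay lower in A than in B bins, with means of -1.38 and 0.09 in *S. acidocaldarius* and -1.17 and 0.19 in *S. islandicus*.

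Maps made from purified DNA without crosslinking showed no compartments in either species. Their strength was 0.00136 in *S. acidocaldarius* and -0.00186 in *S. islandicus*, against 0.221 ± 0.0123 and 0.395 ± 0.00806 in crosslinked log-phase cells (SD, n = 3 each). The ratio of near to far contacts was 0.997 and 1.00 without crosslinking, and 2.35 ± 0.0859 and 5.82 ± 0.246 with it. There was 1 map per species, so these differences have no replicate check.

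Gene by gene, ClsN was low on transcribed genes in both species. Across 2223 *S. acidocaldarius* genes, ClsN occupancy fell with log2(TPM + 1) at r = -0.41 (rho = -0.41, permutation p = 0.00225, adjusted p = 0.0101), and the same held within A genes (r = -0.20, rho = -0.24, permutation p = 0.00505) and within B genes (r = -0.32, rho = -0.33, permutation p = 0.00483). In *S. islandicus* it held across 2643 genes (r = -0.38, rho = -0.37, permutation p = 0.0106, adjusted p = 0.0127) and within B genes (r = -0.29, rho = -0.30, permutation p = 0.00928). Within A genes of *S. islandicus* r was 0.09 and rho 0.12, with a permutation p of 0.0763 for r and 0.0229 for rho. Adjustment was over this family of 6 relations, and genes are not independent.

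Rpo2, the RNA polymerase subunit, lay mostly in A. Its log2 occupancy in log-phase *S. acidocaldarius* was 0.25 in A and -0.70 in B bins, a difference of 0.95. Genes in the top 10% of expression had a mean of 1.18 and those in the lower 50% of expression had -0.93. Across 2221 genes Rpo2 rose with expression (r = 0.66, rho = 0.66, permutation p = 0.00045, the smallest possible) and fell with ClsN (r = -0.38, rho = -0.37, permutation p = 0.00946). Across bins it followed expression (r = 0.87, rho = 0.84), the eigenvector (r = 0.71, rho = 0.74) and, inversely, ClsN (r = -0.72, rho = -0.73), each with the smallest permutation p of 0.00671. Adjusted p-values over the 5 relations were at most 0.00946. The immunoprecipitate held 130355 reads. Without division by input the r with expression across genes was 0.43. That signal was summed over each gene and not divided by its length, so the lower r cannot show how far the relation depends on the input.

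Actinomycin D, which blocks transcription, weakened the compartments of *S. acidocaldarius*. Strength was 0.221 ± 0.0123 in log phase (SD, n = 3), 0.122 ± 0.00894 after 15 min (n = 2) and 0.0784 ± 0.0524 after 30 min (n = 2, libraries at 0.115 and 0.0414). Each treated library lay below every log-phase library. The 30-min maps were shallow, with totals of 5.80 M and 5.15 M, the latter the lowest of all maps. Their replicate correlation of 0.490 was the lowest among the Hi-C replicates. Log-phase replicates 1 and 3, with totals of 6.31 M and 7.37 M, had strengths of 0.207 and 0.226. Totals not far above those of the 30-min maps thus went with strengths near the log-phase mean. No log-phase map was as shallow as the 30-min maps, and whether depth lowered their strengths was not tested directly. At 15 min the A bin at 540001 to 555000 lost preference for A (-0.25, SE 0.02, limma adjusted p = 6.24e-27) and the B bin at 1770001 to 1785000 lost preference for B (0.23, SE 0.02, limma adjusted p = 2.59e-23). In all, 123 of 149 bins changed at 15 min, 120 of them toward a weaker preference (55 A bins lower, 65 B bins higher), and 111 changed at 30 min, each of them toward a weaker preference (47 A bins lower, 64 B bins higher). The bin at 540001 to 555000 also fell furthest at 30 min (-0.33, SE 0.04, limma adjusted p = 4.49e-08). The ratio of near to far contacts was 2.59 ± 0.103 and 2.92 ± 0.248 after 15 and 30 min, against 2.35 ± 0.0859. The exact permutation p for strength and for this ratio was 0.1 at each time, the smallest that 10 splits allow. With only the 20% of bins at each end of the eigenvector the differences in strength were -0.19 at 15 min and -0.29 at 30 min, against -0.10 and -0.14 with all bins. ClsN kept its bias toward B in the single treated libraries, at a B minus A difference of 0.98 after 15 min and 1.06 after 30 min against 1.47 ± 0.34 in log phase (SD, n = 2), with no replicate check on the treated side.

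**Figure D2:**
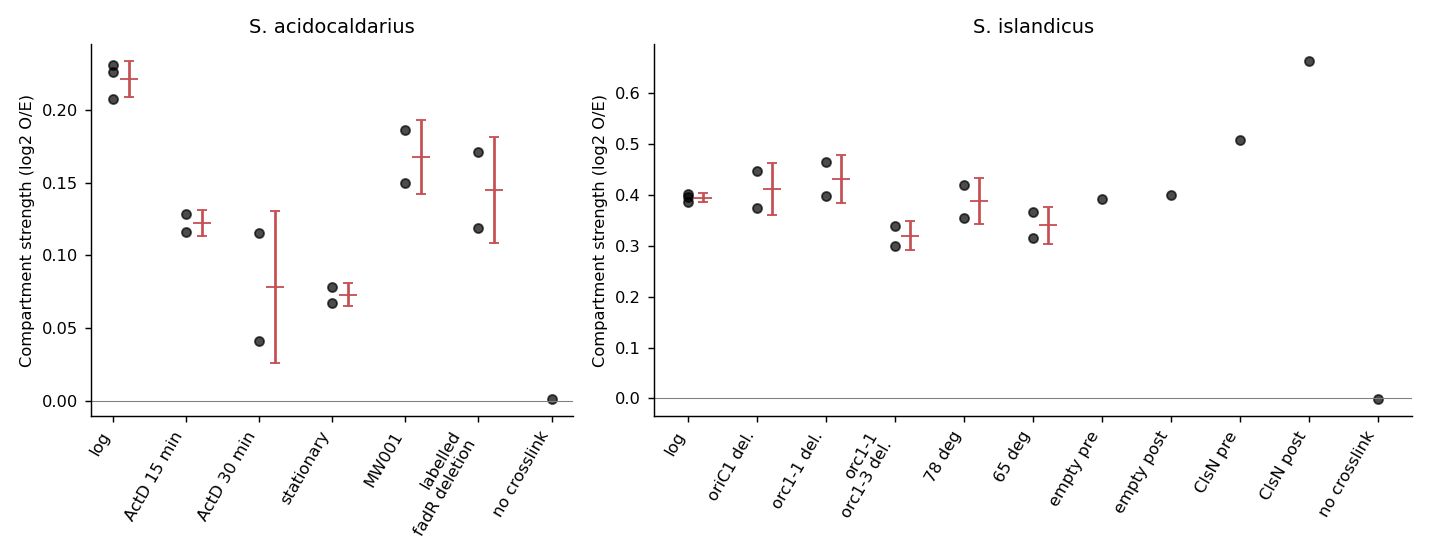
Compartment strength (log2 O/E) of each Hi-C library of *S. acidocaldarius* and *S. islandicus* as points, with the mean and SD of groups of at least 2 libraries as red bars. Strength was 0.221 in log-phase *S. acidocaldarius*, 0.122 and 0.0784 after 15 and 30 min of actinomycin D and 0.0731 in stationary phase, and lay at 0.00136 and -0.00186 without crosslinking.

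Stationary-phase *S. acidocaldarius* had weak compartments. Strength was 0.0731 ± 0.00793 (SD, n = 2), which is 33.0% of the log-phase mean of 0.221 ± 0.0123 (n = 3), and both libraries lay below all 3 log-phase libraries. The B bins at 1830001 to 1845000 (0.32, SE 0.02) and 1755001 to 1770000 (0.32, SE 0.02) lost most of their preference for B, and the A bins at 2205001 to 2220000 (-0.27, SE 0.02) and 2190001 to 2205000 (-0.26, SE 0.02) most of theirs for A, with limma adjusted p-values of at most 3.0e-37. Of 149 bins, 131 changed: 59 A bins fell, 68 B bins rose and 4 A bins rose. Among 11026 bin pairs, 4353 changed in limma, with 1931 of 5544 A-B pairs higher and 263 lower, 677 of 2556 A-A pairs lower and 228 higher, and 1110 of 2926 B-B pairs lower and 144 higher. The positions of A and B were preserved over most of the chromosome, as the eigenvectors of the stationary libraries correlated with that of log phase at 0.850 and 0.875. The sign of the preference turned in 14 of 149 bins, 13 of them among the changed bins. The B bins from 240001 to 315000, with weak log-phase eigenvectors of -0.09 to -0.42, rose by 0.14 to 0.25. The ratio of near to far contacts was 2.05 ± 0.259 against 2.35 ± 0.0859. The exact permutation p for strength and for this ratio was 0.1, the smallest that 10 splits allow. With the 20% of bins at each end the difference was -0.25 against -0.15, and without stationary replicate 1 or 2 the count of changed pairs was 1017 or 1368.

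The transcriptome of stationary cells shifted from A toward B. Of 2176 genes tested, 684 rose and 616 fell (edgeR), 462 and 257 of them more than 2-fold. Among 1008 B genes 480 rose and 185 fell, while among 1168 A genes 204 rose and 431 fell. The mean log2 fold change was 0.81 in B and -0.15 in A, a difference with a rotation permutation p of 0.0211 over 2176 rotations. Neighbouring genes moved together, with 32 runs of at least 5 genes rising (264 genes) and 20 falling (157 genes), against at most 24 and 12 when calls were shuffled 1000 times among A genes and among B genes (permutation p = 0.000999 for each, the smallest possible). The shuffles moved genes singly, and neighbours on a shared transcript would exceed them as well. They therefore cannot tell shared transcripts from changes of a wider region. The B run at 987941 to 999445 (11 genes) rose by 4.34, from a mean of 39.9 to 1747 TPM, and the B run at 278371 to 295081 (21 genes) rose by 3.38, from 442 to 3123 TPM. The longest falling run, 23 A genes at 464657 to 476103, changed by -1.22, from 2538 to 1107 TPM. Saci_2209 (2048878 to 2050065) rose by 6.59 (SE 0.21, edgeR adjusted p = 1.05e-06), from 5.64 ± 0.571 to 559.3 ± 80.7 TPM (SD, n = 2 each), and Saci_2235 (2077650 to 2079509) by 6.29 (SE 0.19, edgeR adjusted p = 1.05e-06). Saci_1701 (1459196 to 1460647) fell by 4.84 (SE 0.23, edgeR adjusted p = 2.31e-06), from 394.0 ± 69.1 to 14.4 ± 2.47 TPM, and Saci_1003 (803952 to 805004) fell by 4.51 (SE 0.31). These 4 genes all lie in B.

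ClsN occupancy in stationary cells moved opposite to transcription. Across 2176 genes, the change in ClsN fell with the change in RNA (r = -0.35, rho = -0.36, permutation p = 0.00551, adjusted p = 0.0134 over 6 relations). The mean ClsN change was negative in 25 of the 32 rising runs and positive in 19 of the 20 falling runs. In the longest rising run (278371 to 295081) it was -1.16 and in the longest falling run (464657 to 476103) 1.05, while it went the other way in 7 rising runs, among them 901175 to 909971 (0.37), and in the falling run at 2037777 to 2042739 (-0.78). Most rising runs lay in B and most falling runs in A, where the B minus A difference of ClsN was also smaller. These signs therefore do not separate genes from compartments, and relations of the changes within A or within B were not tested. Across bins, preference for A rose where ClsN fell (r = -0.69, permutation p = 0.00671, the smallest possible, adjusted p = 0.0134; rho = -0.78, permutation p = 0.0134) and where RNA rose (r = 0.57, rho = 0.65, permutation p = 0.0201, adjusted p = 0.0403 in another family of 6). The B minus A difference of ClsN was 0.80 ± 0.08 against 1.47 ± 0.34 in log phase (SD, n = 2 each), with an exact permutation p of 0.33, the smallest that 6 splits allow. The relations of ClsN with RNA and with preference were -0.23 and -0.44 without log-phase replicate 2, and the B minus A difference changed by -0.43 without that library and by -1.03 with the 20% of bins at each end, against -0.67. Of 2223 genes, 3 neighbours gained ClsN in limma and 66 had an unadjusted p under 0.05: Saci_2092 (1909657 to 1910067, 3.71, SE 0.70, limma adjusted p = 0.000225), Saci_2093 (1910267 to 1910773, 3.37, SE 0.70, limma adjusted p = 0.00151) and Saci_2091 (1909176 to 1909664, 2.97, SE 0.70, limma adjusted p = 0.0151). The median gene changed by 0.19, and no gene passed after centring on it or without stationary replicate 2 or log-phase replicate 2, while 7 passed with the immunoprecipitate share alone.

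**Figure D3:**
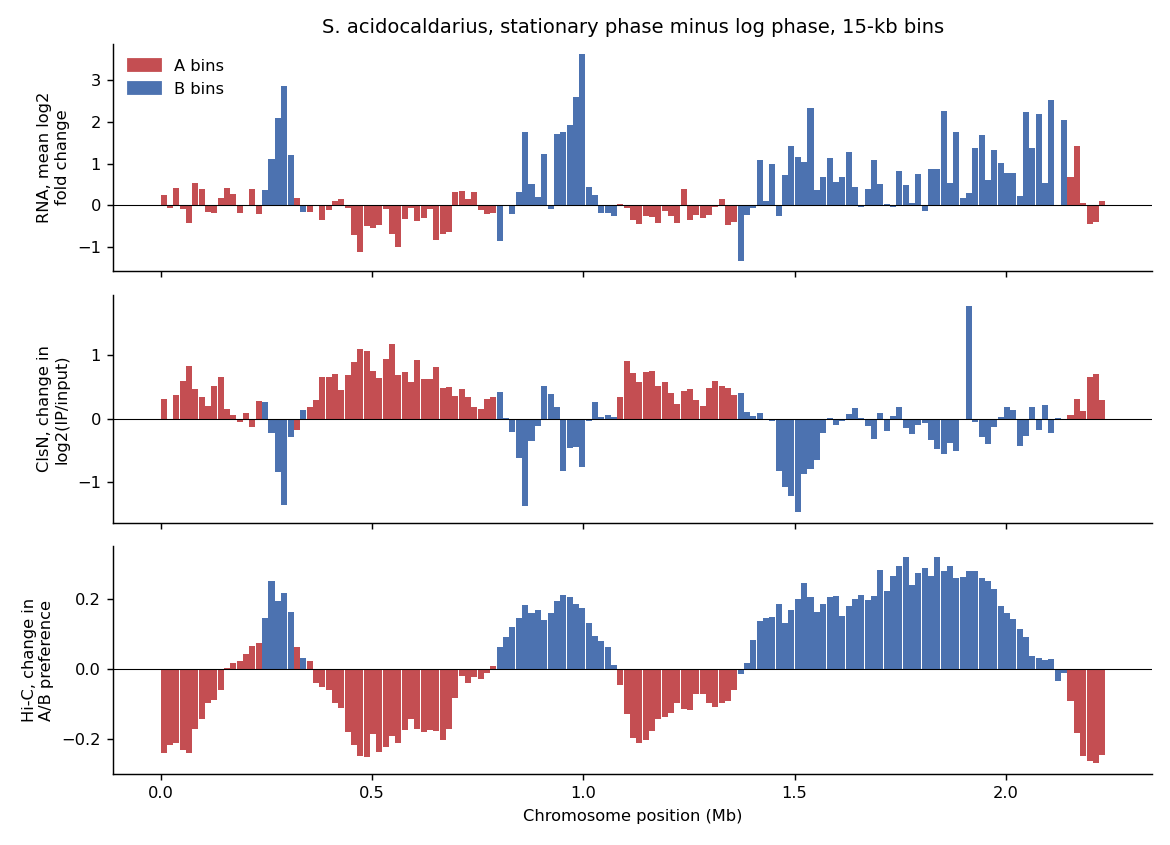
Stationary minus log phase per bin of 15 kb along the *S. acidocaldarius* chromosome (position in Mb), with A bins in red and B bins in blue, for the mean log2 fold change in RNA, the change in log2 ClsN occupancy and the change in A/B preference. Across 149 bins the change in preference had r = -0.69 with ClsN and r = 0.57 with RNA.

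The fadR deletion was compared with its parent MW001. FadR is the transcriptional repressor of a fatty acid gene cluster, Saci_1103 to Saci_1126 (903047 to 931616, in 3 B bins). The deleted gene itself, Saci_1107 (908073 to 908663, 591 bp), went against its label. It had 892.3 ± 1.42 TPM in the libraries labelled fadR deletion and 72.8 ± 2.53 TPM in MW001 (SD, n = 2 each), a log2 fold change of 3.65 (SE 0.10, edgeR adjusted p = 0.000185). Input coverage over the gene was 0.770 and 0.840 of the library median, with 0 bases uncovered, against 0.762 and 0.784 in MW001. Coverage differed at the gene's edges, at 2.05 and 2.28 over 907573 to 908022 against 0.797 and 0.896 in MW001, and at 0.337 and 0.438 over 908623 to 908672 against 0.851 and 0.878. Each direction given here is that of the libraries labelled fadR deletion.

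In the libraries labelled fadR deletion, the fatty acid cluster rose as a block. Of its 24 genes, 19 rose and 0 fell in edgeR (22 rose when adjusted over the list alone), with a mean log2 fold change of 1.44 and a median of 1.34. Saci_1108 (908850 to 909971) rose by 2.40 (SE 0.15, edgeR adjusted p = 0.00347), from 290.3 ± 35.6 to 1491 ± 170 TPM, and the 16 adjacent genes from Saci_1103 to Saci_1118 at 903047 to 923047 each rose, by a mean of 1.80. Outside the cluster, 0 of 2168 genes passed in edgeR, in either direction, with 101 at an unadjusted p under 0.05, and DESeq2 called 4 higher and 3 lower. Among all 2192 genes DESeq2 called 25 higher and 3 lower, and edgeR without MW001 replicate 1 called 30 higher and 110 lower. Same-numbered libraries of the 2 strains deviated alike in RNA (r = 0.47). With the replicate number as a block, edgeR called more genes than the cluster holds, in both directions (counts given below). The 0 outside the cluster therefore depends on leaving the number out of the fit. The cluster's camera p was 2.979e-50 with the preset correlation, and p = 0.0144 with an estimated correlation of 0.142. Over the region, ClsN occupancy was 1.54 and 0.80 in MW001 and 0.26 and 0.25 in the libraries labelled fadR deletion, a change of -0.91. The mean change per gene was -1.06, and 8 of 2223 windows of 24 genes, its own included, fell as much. Without MW001 replicate 1 the change was -0.54. The region's preference for A changed by 0.0913, from -0.302 and -0.277 to -0.223 and -0.174, and 2 of 149 windows of 3 bins rose as much, its own included. Bins at 840001 to 900000, outside the cluster, rose by 0.066 to 0.093, so the rise was not confined to the cluster.

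Chromosome folding as a whole was compared between the same strains. Strength was 0.145 ± 0.0365 in the libraries labelled fadR deletion and 0.168 ± 0.0256 in MW001 (SD, n = 2 each, exact permutation p = 0.667, smallest possible 0.33). The difference of -0.023 became -0.049 or 0.0031 without replicate 1 or 2 labelled fadR deletion and -0.0046 or -0.041 without MW001 replicate 1 or 2. limma called 0 of 149 bins (4 at an unadjusted p under 0.05), 0 of 11026 bin pairs (467 at an unadjusted p under 0.05, 1 called without replicate 1 labelled fadR deletion) and 0 of 2223 genes for ClsN (7 at an unadjusted p under 0.05, 21 called without MW001 replicate 1). Across all bins, which are not independent, the change in preference ran against the eigenvector (r = -0.77, rho = -0.80, permutation p = 0.0201, adjusted p = 0.0314 over 8 comparisons), but with r = 0.20 without replicate 2 labelled fadR deletion. Pairs of replicates within the groups of both species differed along the eigenvector as well, with an absolute r of 0.26 to 0.92 (median 0.80) and a permutation p under 0.05 in 14 of 16 pairs, so this r does not set the strains apart from replicates. The B minus A difference of ClsN was 1.38 ± 0.35 against 1.30 ± 0.59 (SD, n = 2 each, exact permutation p = 1), a difference of 0.08 that was -0.17 or 0.32 without replicate 1 or 2 labelled fadR deletion and 0.49 or -0.34 without MW001 replicate 1 or 2. Across 2192 genes ClsN fell with RNA (r = -0.37, rho = -0.21, permutation p = 0.00137, adjusted p = 0.00821 over 6 relations), at -0.13 without replicate 1 labelled fadR deletion. Across bins r of preference with ClsN was -0.13 (rho = 0.13, permutation p = 0.671), but -0.54 or -0.49 without replicate 1 or 2 labelled fadR deletion and -0.22 or -0.68 without MW001 replicate 1 or 2.

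The replication mutants of *S. islandicus* asked whether an origin (oriC1) or initiator genes (orc1-1, orc1-3) shape compartments. Strength in the orc1-1 orc1-3 deletion was 0.320 ± 0.0287 (SD, n = 2) against 0.395 ± 0.00806 in log phase (n = 3), and both libraries lay below every log-phase library. In that strain 59 of 85 bins changed in limma: 11 A bins fell, 47 B bins rose and 1 B bin fell. Preference for B weakened at 2040001 to 2070000 (0.15, SE 0.02, limma adjusted p = 0.000124) and for A at 1290001 to 1320000 (-0.12, SE 0.02, limma adjusted p = 0.000305). In the oriC1 deletion strength was 0.411 ± 0.0513 (n = 2) and 0 bins passed in limma (1 at an unadjusted p under 0.05), and in the orc1-1 deletion it was 0.432 ± 0.0468 (n = 2) with 0 bins (5 at an unadjusted p under 0.05). Across bins, which are not independent, the change in preference followed the eigenvector in the orc1-1 deletion (r = 0.88, rho = 0.85, permutation p = 0.0118, adjusted p = 0.0235 over the same 8 comparisons; r = 0.22 without its replicate 2) and ran against it in the orc1-1 orc1-3 deletion (r = -0.92, rho = -0.83, permutation p = 0.0235, adjusted p = 0.0314). For oriC1 r was 0.43 (rho = 0.49, permutation p = 0.165, adjusted p = 0.188), and -0.55 without its replicate 2. Replicate pairs of *S. islandicus* gave an absolute r of 0.41 to 0.92, so none of these r sets a strain apart from replicates. The exact permutation p for strength was 0.1, the smallest possible, in the orc1-1 orc1-3 deletion, 0.8 for oriC1 and 0.2 for orc1-1. Counts of changed bins rested on single libraries: 46 and 9 for oriC1 without its replicate 1 or 2, and 63 for orc1-1 without its replicate 1. The difference in strength was 0.05 and -0.02 without replicate 1 or 2 of oriC1, and 0.07 and 0.00 likewise for orc1-1.

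Cold shock of *S. islandicus* from 78 to 65 degrees was examined for contacts, compartments and transcription. The ratio of near to far contacts was 3.16 ± 0.0469 at 65 and 5.69 ± 0.191 at 78 degrees (SD, n = 2 each, exact permutation p = 0.33, the smallest possible). Strength was 0.340 ± 0.0362 against 0.388 ± 0.0456 (exact permutation p = 0.667). Within the long A domain, the edge at 1110001 to 1140000 gained preference for A (0.26, SE 0.05, limma adjusted p = 3.32e-05) while 1380001 to 1410000 lost it (-0.35, SE 0.05, limma adjusted p = 1.62e-08), falling from 0.25 to -0.10. In total 28 of 85 bins changed in limma: 5 A bins fell, 7 A bins rose and 16 B bins rose. Same-numbered libraries deviated alike in preference (r = 0.92), and with the replicate number as a block most bins changed (count given below). Of 3570 bin pairs 1440 changed, with 120 of 351 A-A pairs higher and 55 lower, 128 of 1653 B-B pairs higher and 320 lower, and 481 of 1566 A-B pairs higher and 336 lower. The 28 bins became 7 with pairs at least 10 bins apart, 15 and 8 without 65-degree replicate 1 or 2 and 11 without 78-degree replicate 1, the 1440 pairs became 926 and 787 without 65-degree replicate 1 or 2, and the difference in strength of -0.05 was -0.12 with the 20% of bins at each end, -0.08 without 78-degree replicate 2, -0.07 without 65-degree replicate 1, -0.02 without 78-degree replicate 1 and -0.02 without 65-degree replicate 2.

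RNA changed in 845 of 2488 genes at 65 degrees (edgeR), with 459 higher and 386 lower. Among 906 A genes 205 rose and 91 fell, and among 1582 B genes 254 rose and 295 fell. The mean log2 fold change was 0.10 in A and -0.10 in B (rotation permutation p = 0.303). SiRe_1633 (1519897 to 1521312, A) rose by 2.16 (SE 0.12, edgeR adjusted p = 0.00035), from 474.8 ± 35.2 to 2140.5 ± 84.2 TPM (SD, n = 2 each), and SiRe_2089 (1928367 to 1929770, B) by 1.88 (SE 0.12, edgeR adjusted p = 0.000503). SiRe_2310 (2156925 to 2157644, B) fell by 3.89 (SE 0.60, edgeR adjusted p = 0.00461), from 163.2 ± 124 to 11.2 ± 3.02 TPM, and lies in a run of 11 falling genes at 2154438 to 2163853 with a mean of -2.23. SiRe_0906 (869728 to 870216, B) fell by 3.43 (SE 0.46). Runs of at least 5 genes numbered 16 rising and 9 falling (at most 4 and 3 in such shuffles, permutation p = 0.000999 for each), among them 10 genes at 735678 to 751089 with a mean of -1.58 and 6 genes at 140230 to 146834 with a mean of 0.88, from 4341 to 12337 TPM. Here too the shuffles cannot set shared transcripts apart. Leaving out 65-degree replicate 1 or 2 gave 523 or 396 changed genes.

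ClsN occupancy showed no gene past the threshold at 65 degrees. limma called 0 of 2643 genes (16 at an unadjusted p under 0.05), but 708 without 65-degree replicate 1, and the median gene changed by 0.15. The B minus A difference was 1.05 ± 0.39 at 65 and 1.08 ± 0.15 at 78 degrees (SD, n = 2 each, exact permutation p = 1), a difference of -0.03 that was -0.30 or 0.25 without 65-degree replicate 1 or 2 and 0.07 or -0.13 without 78-degree replicate 1 or 2. Across 2488 genes r of the change in ClsN with that in RNA was 0.03 (rho = 0.03, permutation p = 0.529, adjusted p = 0.635), at 0.12 without 65-degree replicate 1 and -0.20 without replicate 2. Across bins r of preference with ClsN was -0.17 (rho = -0.23, permutation p = 0.2, adjusted p = 0.3), at -0.38 and -0.02 likewise.

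Per the labels, ClsN was overexpressed in *S. islandicus* from an arabinose-inducible plasmid, with an empty plasmid as control. No value here gives the amount of ClsN protein. After 4 h of arabinose, compartment strength went from 0.508 to 0.664 in the ClsN plasmid strain and from 0.392 to 0.40 in the empty plasmid strain. The strains already differed before arabinose. SiRe_0055, with 28.3 times the input DNA of the empty plasmid strain before arabinose, then had 4707 TPM against 875.2 TPM. Whether this gene is the ClsN gene of the plasmid was not tested, so the state before arabinose may not be free of added ClsN. Preference for A was higher in 23 of 27 A bins (mean of all A bins 0.13) and lower in 46 of 58 B bins (mean of all B bins -0.16) in the ClsN plasmid strain, against 12 of 27 (-0.0035) and 44 of 58 (-0.0097) in the empty plasmid strain, so the count of B bins was alike in both. The B bins at 2010001 to 2040000 and 2040001 to 2070000 had the lowest changes (-0.54 and -0.55), and the A bins at 1080001 to 1110000 and 1110001 to 1140000 the highest (0.39 and 0.37). The relative distribution of ClsN hardly moved, with a B minus A difference of 1.42 before and 1.48 after induction, against 1.25 and 1.20 with the empty plasmid. There was 1 library per strain and time, so none of these differences has a replicate check.

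RNA of B genes was lower after ClsN induction. The median log2 change of the 1725 B genes was -0.46 on the log2(TPM + 1) scale, with 1276 of them lower, and lay at percentile 0 of 10000 random lists matched on expression, whose central 95% spanned -0.27 to -0.22. The 919 A genes had a median of 0.09, at percentile 100. More than 2-fold differences numbered 501 lower and 51 higher in B, and 11 lower and 12 higher in A. In the empty plasmid strain the medians were 0.0094 for B and -0.049 for A, which also lay at percentiles 100 and 0 of their matched lists. Lists were drawn from A and B genes together, so the percentiles of A and B mirror each other and make 1 contrast. Since such small medians also reached the extremes, the percentile does not set an effect apart from differences between single libraries. The B bins at 2040001 to 2070000 and 720001 to 750000 had the lowest RNA changes (-1.82 and -1.73). SiRe_1663 went from 14.9 to 293.7 TPM and SiRe_2125 from 64.5 to 635.7 TPM, and both were also higher after arabinose with the empty plasmid (3.70 and 4.87 on the log2 scale). SiRe_0755 went from 287.2 to 15.4 TPM (-4.14) and SiRe_2290 from 220.2 to 14.2 TPM (-3.87), against -0.39 and 0.31 with the empty plasmid. In the empty plasmid strain SiRe_1709 was listed at 0 before and at 93.4 TPM after arabinose, SiRe_2204 at 63.4 TPM before and 0 after, and SiRe_2134 changed by -1.85. A minimum mean of 50 TPM over both libraries gave a median of -0.26 for B genes, and a minimum of 50 TPM before induction gave -0.34. These values compare single libraries, not conditions.

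**Figure D4:**
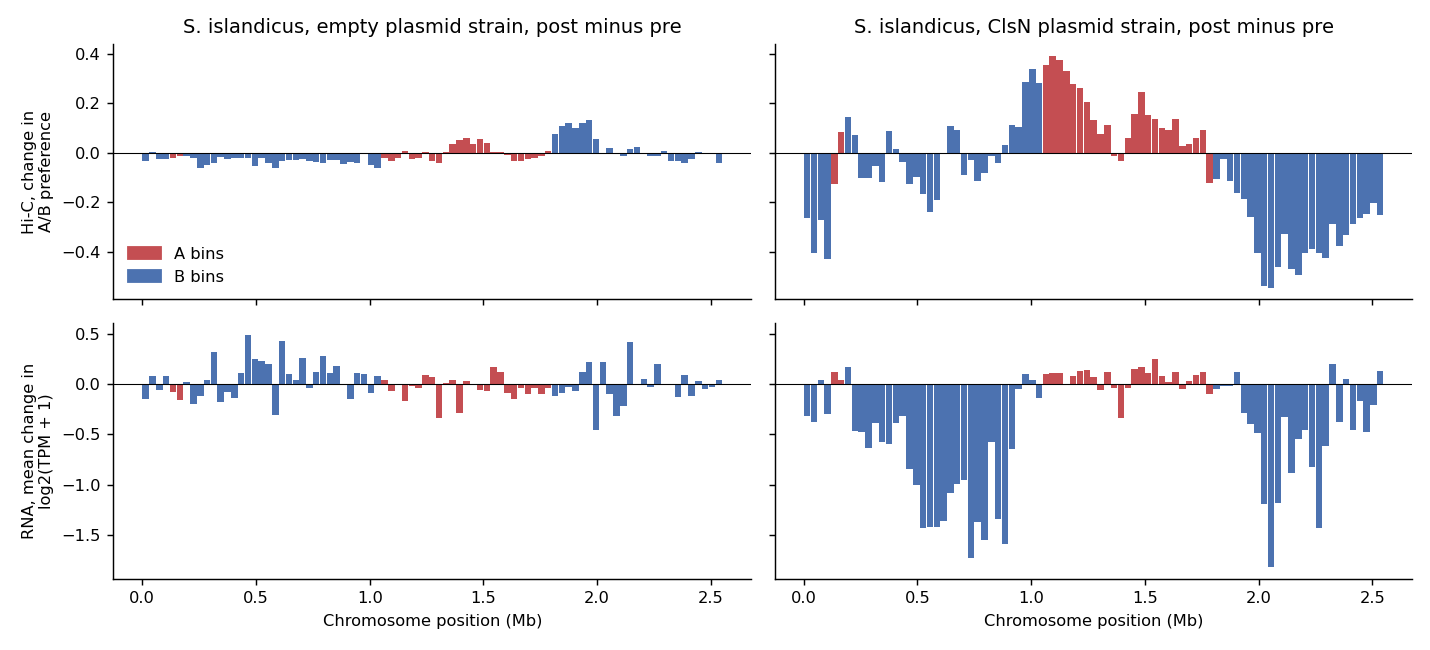
Change after 4 h of arabinose per bin of 30 kb along the *S. islandicus* chromosome (position in Mb) in the empty plasmid and the ClsN plasmid strain, with A bins in red and B bins in blue, for A/B preference and for mean log2(TPM + 1), from 1 library per strain and time. Preference was higher in 23 of 27 A bins and lower in 46 of 58 B bins in the ClsN plasmid strain, and in 12 of 27 and 44 of 58 in the empty plasmid strain, and RNA in the ClsN plasmid strain was lowest at 2040001 to 2070000 (-1.82).

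Marker frequency asked where replication starts once oriC1 is deleted. The log2 ratio of log over stationary phase had 2 maxima, at 1160001 to 1161000 in the A compartment (0.13) and at 2504001 to 2505000 in B (0.10). The smoothed profile spanned 0.27, a 1.20-fold range, with its lowest value from 1952001. Across 85 bins its correlation with the eigenvector was r = 0.34 (permutation p = 0.6; rho = 0.40, permutation p = 0.576). With smoothing over 100 kb there were 3 maxima, a pair on a plateau from 1163001 and 1168001 and another from base 1. There was 1 library per growth phase, so the profile has no replicate check.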

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

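The tests here were chosen after the result was seen, except the mixing of log-phase maps with a flat background and the median of B genes with at least 50 TPM before induction. Stationary-phase compartments were weaker than in log phase (strength 0.0731 against 0.221). A background of random ligation cannot be told apart: log-phase maps mixed with a flat background to the stationary near-to-far ratio kept a strength of at least 0.173, and the 60.9% to 64.4% background needed to reach the stationary strength would leave a ratio of 1.42 to 1.43 where 2.05 was measured. The bound set beforehand took the ratio of true contacts as fixed, but it rose with weaker compartments after actinomycin (2.59 and 2.92 against 2.35), so a background with a raised true ratio stays open. Fewer contacts are argued against, since the smaller stationary map total of 27.1 M exceeded that of 2 of the 3 log-phase libraries. Bins that follow the transcription of their genes would need the correlation of 0.57 found across bins between the changes in preference and RNA, but a uniform weakening would also give a positive correlation where RNA rose more in B than in A (0.81 against -0.15), so this stays open too.

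The RNA of Saci_1107 was raised, not absent, in the libraries labelled fadR deletion. A clean removal of the gene is argued against by input coverage of at least 0.770 of the library median. Swapped labels of the input libraries are argued against, because the stretch at 907573 to 908022 was raised at least 2.29 times over MW001 in the libraries labelled fadR deletion, so these carry an altered locus. Swapped labels of the RNA libraries cannot be told apart from the labels as given by the RNA of the gene, since the lowest of the 4 libraries still had 71.0 TPM and none lacked it, while the rise of 19 of 24 cluster genes (mean 1.44) and the ClsN change of -0.91 over the cluster run the way expected of the labels as given if FadR represses the cluster, which was not tested. A disrupted gene that is still transcribed, for example from a promoter its own product represses, may give such values and was not tested.

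In the ClsN plasmid strain, the mean log2 RNA change after arabinose was -0.59 for B genes and 0.0595 for A genes, against 0.0312 and -0.0467 with the empty plasmid, so that the strains moved in opposite directions in single libraries and the difference was not tested. Arabinose itself cannot be told apart from ClsN with a median of 0.0094 for B genes in the empty plasmid strain, since this is 1 library per time from another culture, while a few genes taking most of the counts are argued against by the gap of 0.55 between the medians of A and B genes. Noise of genes with few counts needed a median above -0.1 among B genes with at least 50 TPM before induction, and -0.34 was found (bootstrap -0.39 to -0.29). The bootstraps here resampled genes as if independent within 1 library per time, so they give no spread between libraries. The median lay below -0.1, but passed the bound of -0.3 set beforehand by less than the spread over genes. The rule for reading this value was changed after it was seen. A minimum mean of 50 TPM over both libraries, which does not favour falls as a minimum before induction does, gave -0.26 (bootstrap -0.32 to -0.21). Whether ClsN, arabinose or a difference between cultures went with the lower RNA of B genes stays open, with 1 library each.

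The B minus A difference of ClsN changed by 0.0561 in the ClsN plasmid strain and by -0.048 in the empty plasmid strain, opposite signs in single libraries whose difference was not tested. Contacts of the plasmid with B over A bins changed by 0.26 on the log2 scale in the ClsN plasmid strain and by -0.014 in the empty plasmid strain, likewise untested. The plasmid sequence, which no comparison between groups used, was enriched in ClsN immunoprecipitate over input by 8.41 and 8.43 times before and after arabinose in the empty plasmid strain and by 6.59 and 7.27 times in the ClsN plasmid strain, where the median chromosomal 1-kb window lay between 0.537 and 0.606.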

How the results depend on the processing

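Of 340 alternative values, 287 were classed as the same, 46 as moved, 5 gained and 1 lost significance, and 1 reversed. A count was classed as the same within 1.5 times, and a strength or other difference within the SD between replicates. A correlation was classed as the same if it stayed on its side of the threshold. This included a turned sign where both p-values were 0.05 or more, so the 287 include such turns. The alternatives for the overexpression, no-crosslink and actinomycin ClsN values and for the number of A bins were added after seeing the data. The cause was not tested for any change given here, apart from the smaller number of libraries when a replicate was left out. The relation of the *S. acidocaldarius* eigenvector with ClsN lost significance as Spearman's rho (-0.66, permutation p = 0.0537).

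With the 20% of bins at each end, differences in strength were -0.19 (actinomycin 15 min), -0.29 (30 min), -0.25 (stationary), -0.10 (orc1-1 orc1-3), -0.12 (65 degrees), 0.20 (ClsN plasmid) and -0.0052 (empty plasmid), and the B minus A difference of ClsN in stationary phase was -1.03. With pairs at least 10 bins apart they were -0.11 (15 min), -0.16 (stationary) and 0.19 (ClsN plasmid), and 7 bins changed at 65 degrees. A and B called in MW001 gave -0.12 in stationary phase. For ClsN genes in stationary phase, the immunoprecipitate share alone called 7 and centring on the median gene 0. The median of B genes after ClsN induction was -0.34 with at least 50 TPM before, -0.26 with a mean of at least 50 TPM and -0.32 with a pseudocount of 10.

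Leaving out single libraries gave differences in strength of -0.11 to -0.09 (actinomycin 15 min), -0.18 to -0.11 (30 min), -0.16 to -0.14 (stationary), -0.0486 to 0.00308 (fadR), -0.0202 to 0.0524 (oriC1), 0.0037 to 0.0699 (orc1-1), -0.0957 to -0.0551 (orc1-1 orc1-3) and -0.08 to -0.02 (65 degrees). Changed bins numbered 111 to 125, 102 to 119, 124 to 133, 0 to 0, 0 to 46, 0 to 63, 47 to 77 and 8 to 32 in the same order, and changed pairs 1017 to 5018 (stationary), 0 to 1 (fadR) and 787 to 1409 (65 degrees). ClsN genes numbered 0 to 2 (stationary), 0 to 21 (fadR) and 0 to 708 (65 degrees), and RNA genes 961 to 1189, 14 to 140 and 396 to 1025. The B minus A difference of ClsN changed by -0.91 to -0.43 (stationary), -0.34 to 0.49 (fadR) and -0.30 to 0.25 (65 degrees). The correlation of ClsN with RNA was -0.31 to -0.23 (stationary), -0.33 to -0.13 (fadR) and -0.20 to 0.12 (65 degrees), where it reversed to -0.20 (permutation p = 0.0124) without 65-degree replicate 2 and passed at 0.12 (permutation p = 0.00236) without replicate 1. That of preference with ClsN was -0.73 to -0.44 (stationary), -0.68 to -0.22 (fadR) and -0.38 to -0.016 (65 degrees). The fadR relation passed without replicate 1 or 2 labelled fadR deletion (-0.54, -0.49) or MW001 replicate 2 (-0.68), and the 65-degree relation without 65-degree replicate 1 (-0.38). The eigenvector relations moved by at most the range -0.68 to -0.66 for ClsN and 0.67 to 0.68 for expression in *S. acidocaldarius*, and -0.76 to -0.76 and 0.65 to 0.65 in *S. islandicus*. A bins numbered 69 to 76 and 27 to 27. In the fatty acid cluster 14 to 22 genes rose, ClsN changed by -1.28 to -0.54 and preference by 0.0667 to 0.116. Where a group kept a lone library, it was assumed to vary like the others.

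Replicates share only a number, with 2 pairs per comparison. With the replicate number as a block, changed bins at 65 degrees numbered 73 and changed RNA genes in the libraries labelled fadR deletion 323 (155 higher, 168 lower), while the block moved no other count by over 1.5 times (127, 92, 136 and 71 bins for actinomycin 15 and 30 min, stationary and orc1-1 orc1-3, 4617 and 2142 pairs for stationary and 65 degrees, 1466 and 1160 RNA genes for stationary and 65 degrees, 2 ClsN genes instead of 3 for stationary, 22 cluster genes). Deviations of same-numbered replicates correlated at 0.94 (fadR), 0.92 (65 degrees), 0.56 (stationary), 0.34 and -0.78 (actinomycin), 0.49, 0.61 and 0.74 (oriC1, orc1-1, orc1-1 orc1-3) for preference, 0.47, 0.05 and 0.13 for RNA of the first 3, and 0.63, -0.03 and -0.23 for ClsN. The Rpo2 values are limited by 1 library and a depth of 3.22 reads per base.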

Other observations

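The test of the Hi-C, RNA and ClsN changes per bin and the values below were chosen after the results were seen. In the plasmid strains, SiRe_0055 (46159 to 47922, 1764 bp) had 28.3 and 15.1 times as much input DNA in the ClsN plasmid strain as in the empty plasmid strain, before and after arabinose, and was the only 1 of 2643 genes over 2-fold at both times. Its RNA went from 4707 to 12315 TPM (2.62-fold) in the ClsN plasmid strain and from 875.2 to 1241 TPM (1.42-fold) in the empty plasmid strain. In cells without a plasmid it had 419.8 TPM at 65 and 1019 TPM at 78 degrees, a log2 fold change of -1.28 (SE 0.12, edgeR adjusted p = 0.00132, n = 2 each). SiRe_1463 (1369626 to 1370030, 405 bp) had 0.0210 and 0.0209 of the 78-degree input coverage in the plasmid strains before and after arabinose and was listed at 0 TPM in all 4 of their RNA libraries. The plasmid sequence was 7282 bp in the empty plasmid strain, at 13.9 and 12.6 times the chromosomal input coverage, and 8941 bp in the ClsN plasmid strain, at 12.7 and 9.90 times.

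After ClsN induction, the B bins next to the long A domain at 960001, 990001 and 1020001 had higher preference for A (0.29, 0.34 and 0.28), unlike most B bins. Across bins, r of preference with RNA was 0.44 in the ClsN plasmid strain and -0.08 in the empty plasmid strain, r of ClsN with RNA was -0.44 and -0.24, and r of preference with ClsN was -0.06 and -0.07, with no test on single libraries.

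Across 149 bins, the change in ClsN fell with the mean change in RNA in stationary phase (r = -0.66, rho = -0.69, permutation p = 0.00671) and in the libraries labelled fadR deletion (r = -0.71, rho = -0.58, permutation p = 0.00671), the smallest p that rotations give, with an adjusted p of 0.0201 in a family of 6. At 65 degrees r was -0.16 (rho = -0.13, permutation p = 0.247) across 85 bins. The change in preference had r = 0.07 with RNA (rho = -0.26, permutation p = 0.678) in the libraries labelled fadR deletion and -0.12 (rho = -0.15, permutation p = 0.812) at 65 degrees.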
